A study of Spirodela polyrhiza with 16 samples.

How the data were processed

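Polyadenylated RNA of 16 pools was sequenced as 150 bp read pairs, per the labels' protocols. The pools were fronds and roots of Spirodela polyrhiza grown with or without phosphate, 4 per group, each from the plants of 1 flask. Reads were aligned with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3, per the submitters' processing notes. The genome build, the annotation and the settings are not given in the sources used here, so coordinates are those of the deposited table. Whether counting used strand is not stated, so reads of the 14 overlapping models and of close copies can be shared. The deposited values are FPKM per the file headers, with a gene length, position, Swiss-Prot homolog and Pfam domains beside each of 20389 genes. The table gives no gene symbols. Genes are named by their identifier and the homolog or domain given for them, which 13558 genes have, and a homolog's name does not show that the gene has its function. Gene lengths were multiples of 3 for 98.4% of genes and are taken as coding length. 1 line of the table was not used here.

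The columns show tissue and treatment and carry a number from 1 to 8 per tissue, 1 to 4 for control and 5 to 8 for no phosphate. The numbers do not show which labelled replicate a column is, so libraries are named by group and column number, and no libraries were paired in the model. In every library 100% of the FPKM values, multiplied by gene length, were whole multiples of 1 step (tolerance 0.001 reads), which gives the whole reads behind them. The library size implied by that step was 0.886 to 1.14 times the sum of the recovered reads, below 1 in fronds and above 1 in roots. The deposited FPKM therefore carry a scaling between libraries that the sources used here do not describe. Recovered reads summed to 6325297 to 12437151 per library. With these depths, 3 reads over a coding length of 1 kb were worth between 0.213 and 0.507 FPKM. No pair of libraries in a group agreed within sampling noise, the chi-square of their reads per degree of freedom being 3.83 or more.

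The unit being FPKM, the branch of the design written for FPKM was used. Values were taken to log2(FPKM + 1), 16598 genes with a mean of at least 0.5 FPKM over the 16 libraries were kept and 3791 were not. A mean per group was fitted over all 16 libraries with limma 3.58.1 in R 4.3.3, with a trended and robust prior (statmod 1.5.0). That leaves 12 residual degrees of freedom. The contrasts were no phosphate minus control in fronds and in roots, their difference, and root minus frond in control medium. P-values are two-sided and adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. Log2 changes on this scale understate the change of low genes.

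The 20 gene lists and the rule for named genes were fixed before the data were examined. Lists were matched by keyword to the homolog names and domains, with no member added or removed by hand, which also takes in genes that only share a word. They were phosphate transport, SPX and phosphate signalling, acid phosphatases, phosphorus scavenging, galactolipid and sulfolipid remodelling, glycolytic bypass and organic acids, nitrate, ammonium and sulfate uptake, iron and metal homeostasis, flavonoids, photosynthesis, starch, ribosomal proteins, DNA replication and cell cycle, root cell markers, aquaporins, heat shock, wound and jasmonate, abscisic acid and dormancy, lignin and suberin, and organelle-named genes. Each was tested with limma's camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the 20 lists. The estimated one called no list in any contrast, photosynthesis between fronds and roots included. A call lost with it therefore does not show that a list was unshifted. Named for fronds, roots and tissues were up to 10 largest rises and 10 largest falls among called genes with a mean of at least 5 FPKM in the higher group, a description and no overlap between the 4 and 4 libraries. For the interaction the 6 largest contrasts each way with that level and a description were named, and for each list up to 4 members with the smallest adjusted p, of which the text gives a part. With 4 against 4 libraries, no overlap arises by chance in 2.86% of genes.

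On simulated data, negative binomial reads were drawn for all 16 libraries from the real group means and library sizes, with 200 changed genes in each of 10 draws over about 16586 tested genes. For the frond comparison 28.2%, 60.8%, 88.8% and 94.8% of genes changed by 1.5, 2, 4 and 8 times were called, and 24.2%, 60.8%, 85.2% and 94% for the root comparison. Calls on unchanged genes made up 7.40% of all calls for fronds and 6.31% for roots, above the nominal 5%. Genes were drawn independently, with a spread per gene pooled over the groups. The draws therefore lack deviations that genes of a library share and the wider spread of roots. Draws without changed genes called at most 1 root gene, while another split of the real root libraries called 1113. The simulated rates may therefore not hold for the real roots. Alternatives were limma without trend and robust prior, FPKM rescaled to the same sum in each library, quantile normalization, a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, only the libraries compared, a change of at least 1, and each library left out. Chosen after the data were seen were limma's voom on the recovered reads with either library size, a fit without 2 root libraries and a block by column number. Figures were drawn with matplotlib 3.10.9.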

Results

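Transcript levels were measured in the giant duckweed Spirodela polyrhiza, clone 9509, a small floating plant whose body is a leaf-like frond with roots hanging into the water. The plants grew in 250 ml flasks with 100 ml of medium. On day 10 the medium was replaced, either by full medium or by medium made without the phosphate salt. On day 11 the plants of each flask were separated into fronds and roots and pooled. The 16 polyadenylated RNA libraries formed 4 groups of 4, which were control fronds, no-phosphate fronds, control roots and no-phosphate roots. Whole reads recovered from the deposited values summed to between 6325297 and 12437151 per library. The means were 7669605 in control fronds, 8111859 in no-phosphate fronds, 7207233 in control roots and 9633438 in no-phosphate roots. Of 20389 gene models, 16598 had a mean of at least 0.5 FPKM and were tested. Levels below are mean FPKM ± SD over the 4 libraries of a group. Log2 changes are on the log2(FPKM + 1) scale with their standard error.

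The first comparison asked which transcripts of the fronds differed 1 day after phosphate was withdrawn. By camera at the preset correlation, 4 of 20 lists were shifted upwards in fronds without phosphate: SPX and phosphate signalling, heat shock, ribosomal proteins, and DNA replication and cell cycle. None was called with an estimated correlation (adjusted p = 0.132, 0.132, 0.700 and 0.555). By limma, 732 of 16598 genes passed an adjusted p of 0.05, of which 351 rose and 381 fell. The change was at least 1 on the log2 scale for 80 of the risen and 87 of the fallen genes, and the median size of the called changes was 0.73.

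Among described genes whose 4 libraries per group did not overlap, the largest rise was that of Sp07g00981 (chromosome 7, 7179020 to 7179780), a homolog of the small heat shock protein of mitochondria, from 6.35 ± 2.18 to 51.2 ± 27.9 FPKM, a log2 change of 2.70 ± 0.55 (SE; adjusted p = 0.0152). An ethylene-responsive factor 15 homolog, Sp09g00136, rose from 3.44 ± 2.28 to 26.5 ± 24.5 FPKM. A NAC-domain transcription factor, Sp01g01216, rose from 0.705 ± 0.254 to 8.16 ± 9.33 FPKM. No-phosphate library 6 carried both means, which were 14.4 and 3.52 FPKM without it, and neither gene was called when it was left out (adjusted p = 0.107 and 0.0934). Sp06g01336 (chromosome 6, 8296160 to 8298840), a homolog of chloroplast cis-prenyltransferase 4, which makes polyprenyl chains, rose from 102 ± 42.5 to 466 ± 156 FPKM with a log2 change of 2.22 ± 0.39 (SE; adjusted p = 0.00815). Both homologs of 5'-adenylylsulfate reductase 3, a reductive step of sulfate assimilation, rose. Sp17g00278 went from 208 ± 53.9 to 989 ± 519.8 FPKM and Sp13g00992 from 27.4 ± 7.03 to 114 ± 36.8 FPKM, with log2 changes of 2.11 ± 0.45 (SE; adjusted p = 0.0174) and 2.00 ± 0.31 (SE; adjusted p = 0.00432). The other large rises were L-aspartate oxidase, which opens NAD synthesis (Sp05g00464, 12.2 ± 5.21 to 45.0 ± 14.6 FPKM), the phosphatase DSP1 (Sp05g00658, 22.9 ± 6.71 to 78.1 ± 9.74 FPKM), a late embryogenesis abundant protein (Sp18g00034, 15.2 ± 4.16 to 58.1 ± 31.3 FPKM) and a Rubisco activase (Sp01g01702, 1474 ± 399 to 4792 ± 1173 FPKM).

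The largest fall was that of a copper transporter 1 homolog, Sp06g01303 (chromosome 6, 8168110 to 8168510), from 85.7 ± 59.8 to 8.59 ± 5.91 FPKM, a log2 change of -3.14 ± 0.82 (SE; adjusted p = 0.0414). A neighbouring homolog of the same transporter, Sp06g01301, fell from 255 ± 131 to 50.4 ± 24.2 FPKM. The 2 are close copies between which reads could be split. Sp20g00272, a homolog of PRR95, a pseudo-response regulator of the circadian clock, fell from 22.3 ± 10.5 to 3.40 ± 1.55 FPKM with a log2 change of -2.36 ± 0.51 (SE; adjusted p = 0.0180). PLANT CADMIUM RESISTANCE 8 (Sp08g00804) fell from 16.1 ± 5.81 to 2.99 ± 2.40 FPKM (1.86 without no-phosphate library 8), and the calcium pump ATPase 10 (Sp03g00393) from 7.97 ± 2.60 to 2.05 ± 0.736 FPKM. A stress-responsive A/B barrel protein (Sp18g00139) fell from 8.12 ± 3.66 to 0.508 ± 0.462 FPKM and a hydrophobic seed protein (Sp02g01212) from 78.2 ± 24.7 to 19.7 ± 7.18 FPKM. Falls were also called for alanine-glyoxylate aminotransferase, an enzyme of photorespiratory-type metabolism (Sp01g01360, 272 ± 176 to 69.9 ± 21.6 FPKM), a pentatricopeptide repeat protein (Sp01g00127, 9.04 ± 1.90 to 2.25 ± 0.415 FPKM) and chloroplast dnaJ 8 (Sp05g00928, 615 ± 125 to 212 ± 51.9 FPKM).

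**Figure D1:**
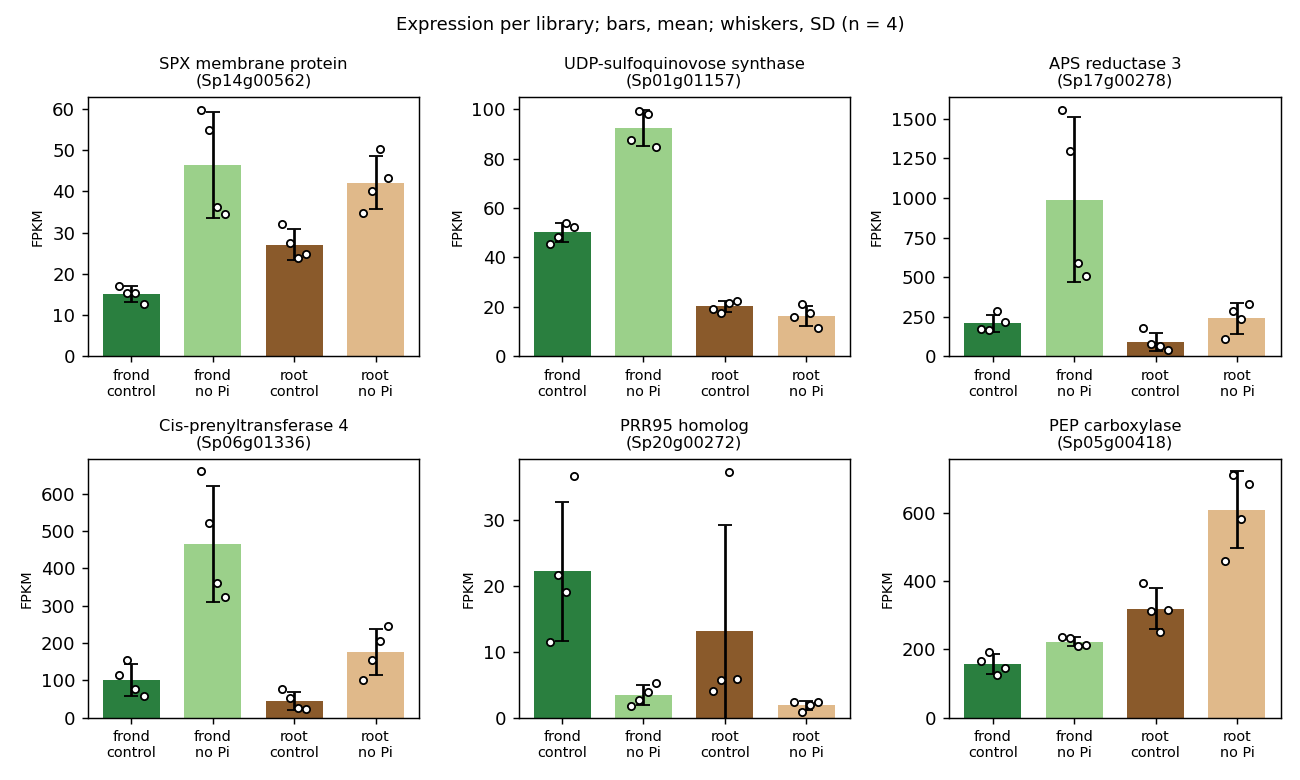
FPKM of 6 genes in the 4 groups, on a linear axis from 0. Bars are means, whiskers the SD and circles the 4 libraries of each group. The 3 upper genes and cis-prenyltransferase 4 rose in fronds and the PRR95 homolog fell, and phosphoenolpyruvate carboxylase and cis-prenyltransferase 4 rose in roots.

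Among the lists tied to phosphate, SPX and phosphate signalling had 3 of 20 members risen and 1 fallen, or 6 and 2 adjusted over the list alone. SPX domains bind inositol pyrophosphates and report the phosphate state of the cell. The 2 SPX membrane proteins Sp14g00562 (15.1 ± 1.86 to 46.4 ± 12.9 FPKM) and Sp14g00561 (11.6 ± 2.22 to 27.3 ± 8.41 FPKM) and SPX3 (Sp08g00151, 4.93 ± 1.66 to 15.2 ± 5.97 FPKM) rose, with log2 changes of 1.53, 1.14 and 1.41. PHOSPHATE STARVATION RESPONSE 2, a transcription factor of the pathway, fell (Sp09g00058, 20.6 ± 1.62 to 14.1 ± 2.30 FPKM). The list as a whole was shifted upwards by camera (adjusted p = 0.0388, and adjusted p = 0.132 with an estimated correlation). The estimated correlation was -9.94e-05, below the preset 0.01, so correlation among the genes of the list does not account for the higher value. The keywords of the list also took in a photolyase-type PHR protein.

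In the galactolipid and sulfolipid list, 3 of 27 members rose and 0 fell (4 and 0 adjusted over the list alone). UDP-sulfoquinovose synthase, which makes the head group of sulfolipid, rose from 50.1 ± 3.87 to 92.4 ± 7.46 FPKM (Sp01g01157, log2 change 0.87 ± 0.14 (SE; adjusted p = 0.00682)). So did the neighbouring digalactosyldiacylglycerol synthases Sp04g00246 (24.1 ± 5.93 to 45.9 ± 6.56 FPKM) and Sp04g00247 (56.8 ± 7.70 to 89.4 ± 9.50 FPKM). The list median was -0.13 while its mean was 0.02, and camera found no shift (adjusted p = 0.989). Of 22 phosphorus-scavenging genes, 3 rose and 1 fell, with the same counts over the list alone. Soluble inorganic pyrophosphatase 4 rose from 87.2 ± 16.4 to 179.5 ± 15.3 FPKM (Sp06g01233) and the phosphodiesterase GDPD6 from 21.5 ± 3.30 to 38.8 ± 8.58 FPKM (Sp03g00551). Bifunctional nuclease 2 fell from 255 ± 33.8 to 134 ± 33.4 FPKM (Sp19g00323). Acid phosphatases had 5 risen and 1 fallen of 44 (7 and 4 over the list alone), among them inactive purple acid phosphatase 27 (Sp10g00286, 12.7 ± 2.27 to 20.6 ± 3.10 FPKM). Further risen members were 2 membrane proteins of a divergent family that shares the keyword PAP2. In the phosphate transport list 2 members rose and 4 fell of 46 (7 and 5 over the list alone). The plastid phosphate transporter 2-1 rose (Sp16g00394, 61.9 ± 2.95 to 92.5 ± 12.1 FPKM). Glucose-6-phosphate/phosphate translocator 2, which carries sugar phosphate into plastids, fell (Sp17g00348, 326 ± 33.0 to 202 ± 31.0 FPKM). The list also held sugar-nucleotide carriers and stress-gated channels by keyword. Camera gave adjusted p = 0.244, 0.748 and 0.155 for these 3 lists.

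Nitrate, ammonium and sulfate uptake had 5 of 35 members risen and 0 fallen (9 and 2 over the list alone), with camera at adjusted p = 0.118. Sulfate transporter 1.3 rose from 53.4 ± 10.3 to 115 ± 10.5 FPKM (Sp07g01016), nitrate transporter 2.3 from 62.1 ± 11.3 to 96.3 ± 17.9 FPKM (Sp08g00312) and its activating partner from 653 ± 101 to 1077 ± 187 FPKM (Sp16g00432). Glycolytic bypass and organic acid genes had 3 risen and 1 fallen of 32 (4 and 3 over the list alone, camera adjusted p = 0.249). NADP-malic enzyme rose (Sp13g00553, 47.4 ± 5.88 to 86.5 ± 8.62 FPKM) and a subunit of the pyrophosphate-dependent phosphofructokinase fell (Sp12g00184, 214 ± 24.3 to 122 ± 28.2 FPKM). Iron and metal genes had 1 risen and 1 fallen of 30 (2 and 2 over the list alone, camera adjusted p = 0.419), the iron transporter Fe(2+) transport protein 2 going from 41.4 ± 7.45 to 91.7 ± 12.3 FPKM (Sp17g00168).

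Heat shock and protein folding, a list meant to show handling stress, had the most called members, 13 risen and 0 fallen of 76 (29 and 4 over the list alone). A stromal HSP70 rose from 46.0 ± 5.25 to 120.4 ± 31.2 FPKM (Sp11g00106) and the endoplasmic reticulum chaperone BIP1 from 66.0 ± 3.35 to 112 ± 9.26 FPKM (Sp20g00077). Camera placed the list upwards at adjusted p = 1.31e-05, and at adjusted p = 0.132 with an estimated correlation. Ribosomal proteins were shifted upwards as a list of 260 with a median log2 change of 0.29 (adjusted p = 6.07e-10), although 2 members rose and 1 fell singly, and the estimated correlation gave adjusted p = 0.700. DNA replication and cell cycle genes were also shifted upwards (median 0.13, adjusted p = 0.0329, and adjusted p = 0.555 with an estimated correlation), with 1 of 112 called, the replication licensing factor MCM5 (Sp05g00898, 3.23 ± 0.601 to 7.54 ± 0.754 FPKM). Of 70 photosynthesis genes 4 rose, among them the photoprotective photosystem II 22 kDa protein (Sp16g00114, 2722 ± 545 to 5387 ± 682 FPKM), and 0 fell. Starch metabolism had 1 risen and 2 fallen of 36, with alpha-glucan water dikinase, which starts starch breakdown, going from 32.0 ± 4.82 to 14.8 ± 5.09 FPKM (Sp08g00310).

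The remaining frond lists held few called genes and no camera call. Risen and fallen members numbered 2 and 0 of 34 for flavonoid synthesis, 0 and 5 of 78 for root cell markers, and 1 and 0 of 22 for aquaporins. They numbered 1 and 2 of 106 for wound and jasmonate genes, 2 and 0 of 51 for abscisic acid and dormancy, and 0 and 0 of 54 for lignin and suberin. For organelle-named genes, all on the 20 nuclear chromosomes, they numbered 3 and 0 of 86. The split of frond calls moved with the scaling: with FPKM rescaled to the same sum in each library, 239 genes were higher and 588 lower, against 351 and 381. The count fell to 153 without no-phosphate frond library 5, 167 without control library 4, 229 without no-phosphate library 6, 308 and 374 without control libraries 2 and 1, and 466 without no-phosphate library 7. It was 1772 when the 8 frond libraries were fitted alone.

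The second comparison asked the same of the roots. Fewer root genes passed: 70 of 16598 genes were called, 59 higher and 11 lower without phosphate. That split moved with the libraries and the scaling. It was 145 higher and 178 lower without no-phosphate library 6, 16 and 9 with FPKM rescaled to the same sum in each library, and 50 and 37 with voom on summed reads, an alternative chosen after the data were seen. The risen genes included cis-prenyltransferase 4 again (Sp06g01336, 44.7 ± 25.1 to 176 ± 62.8 FPKM, log2 change 2.04 ± 0.39 (SE; adjusted p = 0.0344)), a heat shock protein 83 homolog (Sp02g01176, 0.947 ± 0.480 to 6.24 ± 2.72 FPKM) and the plastid phosphoenolpyruvate/phosphate translocator 2 (Sp13g00366, chromosome 13, 1798500 to 1803050, 14.7 ± 7.41 to 46.4 ± 10.5 FPKM, log2 change 1.70 ± 0.29 (SE; adjusted p = 0.0280)). Inositol-3-phosphate synthase, the first step of inositol synthesis, rose from 31.5 ± 11.1 to 84.3 ± 20.03 FPKM (Sp04g01322), and GDP-L-galactose phosphorylase 1, which commits sugar to ascorbate, from 34.3 ± 6.61 to 86.3 ± 22.8 FPKM (Sp07g00503). The 70 kDa peptidyl-prolyl isomerase (Sp16g00326, 34.5 ± 8.48 to 84.0 ± 27.3 FPKM), an NADH-ubiquinone reductase subunit (Sp07g00771, 13.8 ± 6.79 to 38.6 ± 11.8 FPKM), a serine hydrolase (Sp07g00968, 42.3 ± 3.94 to 104 ± 37.7 FPKM), peptidyl-tRNA hydrolase ICT1 (Sp20g00314, 10.6 ± 4.27 to 23.4 ± 5.20 FPKM) and a chloroplast thioredoxin-like protein (Sp04g01215, 184 ± 25.3 to 362 ± 55.4 FPKM) completed the largest rises.

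The described root genes that fell without overlap between groups were 8. They were hydrolase tropI (Sp04g00300, 15.9 ± 9.88 to 4.41 ± 1.47 FPKM), GABA transporter 1 (Sp11g00141, 6.53 ± 1.63 to 2.44 ± 0.608 FPKM), EID1-like F-box protein 2 (Sp09g00997, 13.0 ± 2.43 to 5.72 ± 1.68 FPKM) and mitochondrial glycine-tRNA ligase (Sp11g00133, 35.4 ± 11.3 to 16.2 ± 0.870 FPKM). Smaller falls were those of RNA helicase 53 (Sp17g00062, 21.4 ± 3.53 to 13.0 ± 1.28 FPKM), ribonuclease J (Sp10g00229, 10.1 ± 1.43 to 6.21 ± 0.547 FPKM), the clock-related TIME FOR COFFEE (Sp01g00268, 22.4 ± 1.81 to 15.6 ± 2.43 FPKM) and inositol-tetrakisphosphate 1-kinase 5 (Sp09g00677, 15.8 ± 1.29 to 11.0 ± 0.593 FPKM).

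Among the root lists, camera placed 4 upwards and 2 downwards. Glycolytic bypass and organic acids were up (adjusted p = 0.0185), with 1 of 32 called over all genes, phosphoenolpyruvate carboxylase (Sp05g00418, 318 ± 59.7 to 608 ± 113 FPKM, log2 change 0.93 ± 0.17 (SE; adjusted p = 0.0287)), and 8 adjusted over the list alone. Phosphorus scavenging (adjusted p = 0.0463, 0 called and 4 over the list alone), starch (adjusted p = 0.0165, 0 and 5) and heat shock (adjusted p = 8.54e-05, 2 and 15 risen, with 3 fallen over the list alone) were also up. DNA replication and cell cycle (median -0.12, adjusted p = 0.0189) and root cell markers (median -0.18, adjusted p = 0.0405) were down, with no member called in either. With an estimated correlation the adjusted p of these 6 lists was 0.150, 0.225, 0.333, 0.150, 0.333 and 0.421, so that no list call held. At the preset correlation, phosphorus scavenging lost its call in 13 of 21 alternatives and root cell markers in 7, against 3 or fewer for the other 4 lists. In the other lists the called genes included ALTERED PHOSPHATE STARVATION RESPONSE 1 (Sp01g01152, 23.5 ± 3.81 to 42.7 ± 8.68 FPKM), sulfate transporter 3.1 (Sp03g01231, 2.81 ± 0.817 to 5.74 ± 0.516 FPKM) and a dehydrin (Sp02g00888, 108 ± 9.62 to 181 ± 17.0 FPKM), all risen.

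The root count is weakly determined. It was 0 when the 8 root libraries were fitted alone, 0 without no-phosphate library 7 or 8, 1 without control library 3, 4 without control library 2 and 16 without control library 4. It was 346 without control library 1, 791 without no-phosphate library 5 and 323 without no-phosphate library 6. Of 26 genes with at least 20 FPKM in control fronds and at most 0.2 FPKM in each control root library, 20 were above 0 in no-phosphate root library 5, at a median of 0.967% of the frond level, against 2 to 4 of them in no-phosphate libraries 6 to 8. In control root libraries 1 to 4, 3, 2, 9 and 3 of them were above 0, although the choice itself kept them low there. Among the genes with the largest excess in fronds, named below, control library 3 also raised the root mean of all but ABCG11. Its level was 77.5 FPKM for ABP19a (other control root libraries 3.49 to 16.5) and 5.55 FPKM for protodermal factor 1 (others 0.566 to 2.19). Frond signal is therefore not shown to be particular to library 5. On the first component of the root libraries, control library 1 and no-phosphate library 5 each lay nearer the other group, while on the genes called in fronds library 1 (-0.0709) lay beside controls 2 and 4 (-0.0959 and -0.107) and control library 3 farthest out (-0.357). Without libraries 1 and 5, an alternative chosen after the data were seen, 1604 genes passed, 912 higher and 692 lower.

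**Figure D2:**
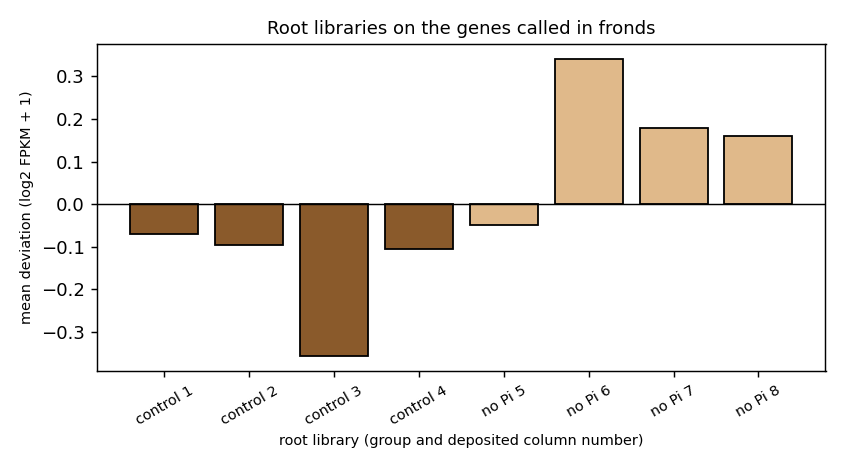
Mean deviation of each root library, on the log2 scale, over the 732 genes called in fronds, signed by their frond change, for control libraries 1 to 4 and no-phosphate libraries 5 to 8. No-phosphate libraries 6 to 8 lie between 0.161 and 0.341, and library 5 lies at -0.0504, near control library 1 at -0.0709.

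**Figure D3:**
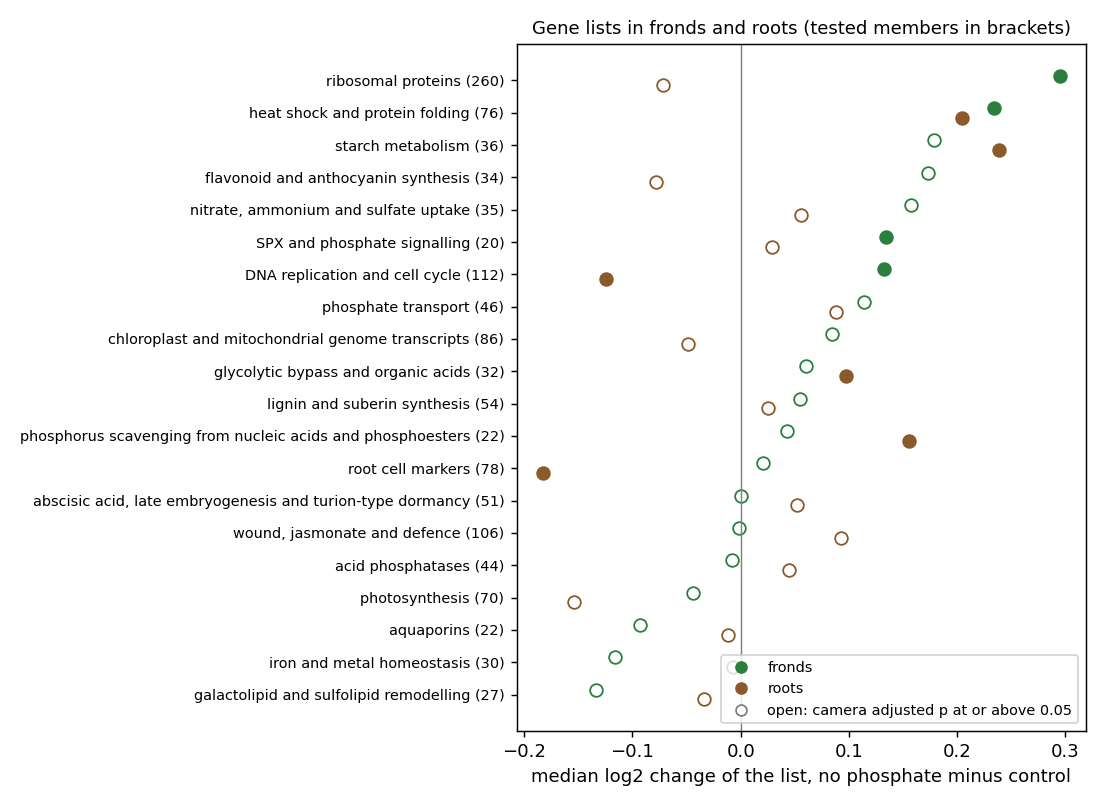
Median log2 change of each of the 20 gene lists, no phosphate minus control, in fronds (green) and roots (brown). Filled circles passed camera at an adjusted p of 0.05 with the preset correlation, and the ribosomal protein list had the medians 0.29 in fronds and -0.07 in roots.

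The responses of both tissues were then set against each other. Across 16598 genes the log2 changes correlated with Pearson r = 0.34 (jackknife SE 0.210 over the libraries) and Spearman rho = 0.27, and r was 0.173 without no-phosphate root library 6. Genes are not independent replicates. The covariance was 0.0410 against a mean of 0.00194 ± 0.0136 (SD) when the treatment labels were permuted within each tissue. Of 100 permutations drawn beside the real labels, 1 gave as high a covariance, while 6 gave as high an r. Genes called higher in both tissues numbered 29, against 1.25 for independent lists of 351 and 59 genes, and genes called lower in both numbered 3, against 0.25. With the treatment permuted within each tissue and as many top genes taken, the overlap was at most 9 upwards. Downwards 4 of 100 permutations gave 3 or more (highest 4), or 5 of 35 with both tissues permuted together by column number. Both downward counts include the real labels. No gene was called in opposite directions.

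The interaction, root response minus frond response, called 0 genes by limma, with 1843 at an unadjusted p under 0.05, where 829.9 are expected for independent genes and 8 of 100 permutations of the treatment within tissues gave as many (highest 2792). Without no-phosphate root library 6 it called 116 genes, 39 higher and 77 lower. It called 2 with FPKM rescaled to the same sum in each library, and 2 with the block by column number, chosen after the data were seen. The 6 largest positive contrasts among described genes at 5 FPKM or more were a cobalamin-independent methionine synthase (Sp09g00776, 3.21), PLANT CADMIUM RESISTANCE 8 (Sp08g00804, 2.65), an NPR1-interacting protein (Sp05g00575, 2.52), a protease inhibitor (Sp03g00871, 2.47), the hydrophobic seed protein Sp02g01212 (2.39) and the calcium-binding KRP1 (Sp17g00525, 2.19). The 6 largest negative ones were chloroplast carbonic anhydrase (Sp05g00466, -1.80), an rRNA methyltransferase (Sp10g01041, -1.66), a root cap protein (Sp09g00203, -1.51), the NAC factor Sp01g01216 (-1.49), expansin A7 (Sp01g01671, -1.47) and histone H3.2 (Sp19g00103, -1.47). Their adjusted p ran from 0.226 to 0.465, so none of the 12 was told apart from 0 with all 16 libraries. As lists, ribosomal proteins (median -0.36, adjusted p = 3.83e-11), DNA replication and cell cycle (median -0.27, adjusted p = 1.41e-05) and flavonoid synthesis (median -0.31, adjusted p = 0.0402) were lower in the root than in the frond response. Flavonoid synthesis lost its call in 10 of 21 alternatives, and the other 2 in none. With an estimated correlation their adjusted p was 0.827, 0.597 and 0.827.

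The last comparison set roots against fronds in full medium. By camera at the preset correlation, lignin and suberin synthesis was higher in roots, and photosynthesis, ribosomal proteins, starch metabolism and organelle-named genes were lower. None of the 5 was called with an estimated correlation (adjusted p = 0.819, 0.775, 0.819, 0.819 and 0.738), and lignin and suberin also lost its call with FPKM rescaled to the same sum in each library. By limma 9929 genes passed, 4785 higher and 5144 lower in roots, and 1970 and 2634 of them by at least 1 on the log2 scale. The largest excess in roots was that of an organic cation/carnitine transporter 1 homolog, Sp14g00298 (chromosome 14, 1686240 to 1688010), from 0.704 ± 0.112 to 178 ± 22.3 FPKM, and of the nodulin-type transporter Sp01g00601, from 1.61 ± 0.505 to 241 ± 14.2 FPKM. The AT-hook protein Sp13g00044 (1.04 ± 0.297 to 133 ± 18.1 FPKM), tonoplast aquaporin TIP1-2 (Sp01g01589, 9.50 ± 3.91 to 530.0 ± 276 FPKM), transcription factor TGAL4 (Sp16g00028, 3.24 ± 0.881 to 186 ± 30.8 FPKM) and a further nodulin-type transporter (Sp18g00412, 11.8 ± 1.27 to 566 ± 89.7 FPKM) followed. The endopeptidase CEP1 (Sp09g00643, 1.07 ± 0.714 to 85.2 ± 27.0 FPKM), the manganese transporter Nramp5 (Sp16g00127, 2.75 ± 1.14 to 137 ± 17.7 FPKM), endoglucanase 20 (Sp19g00214, 9.01 ± 3.33 to 369 ± 93.1 FPKM) and a phospholipase A1 (Sp08g00623, 1.87 ± 0.960 to 104 ± 27.6 FPKM) were the rest of the 10.

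The largest excess in fronds was that of tonoplast aquaporin TIP1-1 (Sp20g00057, chromosome 20, 281141 to 281777), from 747 ± 60.2 to 1.09 ± 1.54 FPKM between fronds and roots, and of auxin-binding protein ABP19a (Sp04g01473), from 6290.3 ± 1117 to 26.8 ± 34.3 FPKM. A lipid-transfer protein (Sp07g00653, 534 ± 69.2 to 0.548 ± 0.695 FPKM), an aspartyl protease (Sp12g00463, 465 ± 39.5 to 0.719 ± 1.39 FPKM), galactinol synthase 1 (Sp13g00367, 487 ± 76.8 to 0.783 ± 1.16 FPKM) and a pollen Ole e I-like protein (Sp02g00736, 289 ± 41.6 to 0.325 ± 0.650 FPKM) followed. The 10 also included a second lipid-transfer protein (Sp10g00918, 308 ± 59.6 to 0.667 ± 1.33 FPKM), protodermal factor 1 (Sp08g00486, 566 ± 52.5 to 2.41 ± 2.20 FPKM) and the cutin exporter ABCG11 (Sp02g00487, 348 ± 79.4 to 0.945 ± 0.568 FPKM). The BURP-domain gene Sp08g00770 went from 178 ± 30.8 to 0.0351 ± 0.0701 FPKM, and at such low levels the log2 changes depend on the pseudocount. Control root library 3 raised the root mean by over 1.5 times for 9 of these 10 genes, all but ABCG11. Without it the means were 0.365 for TIP1-1, 9.84 for ABP19a, 0.216 and 0 for the lipid-transfer proteins, 0.0247 for the protease, 0.205 for galactinol synthase, 0 for the Ole e I-like and BURP genes and 1.36 FPKM for protodermal factor 1.

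Photosynthesis genes were lower in roots for 56 of 70 and higher for 6 (camera adjusted p = 1.16e-08). The frond-rich Rubisco activase Sp10g01056 went from 18504 ± 1715 to 3781 ± 580.0 FPKM, while a Rubisco small subunit gene (Sp15g00063, 24.9 ± 3.43 to 573 ± 54.3 FPKM) and the ferredoxin-NADP reductase Sp06g01202 (144 ± 34.3 to 1357 ± 266 FPKM) were higher in roots. Ribosomal proteins were lower in roots for 168 of 260 and higher for 7 (adjusted p = 1.16e-08), among them the plastid L3-1 (Sp06g00659, 519 ± 18.9 to 132 ± 7.53 FPKM). Starch metabolism was lower (20 of 36, adjusted p = 0.0146), as were organelle-named genes (57 of 86, adjusted p = 1.06e-06). Lignin and suberin synthesis was higher (28 of 54, 14 lower, adjusted p = 0.0224), with the paired 4-coumarate-CoA ligases Sp15g00069 (36.1 ± 3.22 to 261 ± 53.6 FPKM) and Sp15g00070 (37.2 ± 2.49 to 260.5 ± 55.0 FPKM). None of these 5 list calls held with an estimated correlation. Photosynthesis, with 56 of 70 members called lower, was among them, so that setting cannot tell shifted lists from unshifted ones here.

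Lists without a camera call held members that went both ways between the tissues. Among phosphate transport genes 21 of 46 were higher in roots and 14 lower, and PHO1, which loads phosphate into the xylem, went from 23.4 ± 0.789 to 152 ± 17.4 FPKM (Sp02g00083). Of 44 acid phosphatases 18 were higher and 15 lower, with purple acid phosphatase 8 going from 48.1 ± 12.3 to 399 ± 53.5 FPKM (Sp04g01430). Root cell markers had 28 higher and 36 lower of 78, with peroxidase 47 (Sp04g00557, 9.44 ± 1.34 to 187 ± 57.7 FPKM) and peroxidase 45 (Sp12g00830, 3.97 ± 1.13 to 83.8 ± 21.0 FPKM) among the higher. Non-specific phospholipase C4 (Sp11g00243, 5.38 ± 1.61 to 187 ± 51.1 FPKM), nitrate transporter 2.3 (Sp08g00312, 62.1 ± 11.3 to 313 ± 8.53 FPKM) and metal tolerance protein 7 (Sp13g00300, 3.22 ± 0.472 to 65.7 ± 0.830 FPKM) were higher in roots, and sulfate transporter 3.1 (Sp03g01231, 58.2 ± 4.01 to 2.81 ± 0.817 FPKM) lower. Rescaling FPKM to the same sum in each library moved the median of all genes from -0.02 to 0.22 and the calls to 6644 higher and 3785 lower in roots. The lignin and suberin list was then no longer called, so directions between the tissues are relative to the scaling of the deposited values.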

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

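The tests of explanations in this part were chosen after the results were seen. Of 244 groups of 4 libraries of named genes and depths, 23 had 1 library far from the other 3, where chance gives about 12.2 (1 in 20) for normally distributed values. FPKM were used untransformed, and in some flagged groups the other 3 libraries were at 0. That rate may therefore not hold, and no excess over chance is claimed. In the no-phosphate groups, library 6 was high for the NAC factor Sp01g01216 in fronds (22.1 FPKM, others 2.47 to 4.58) and in roots (4.89, others 0.132 to 0.555), for Sp09g00136 in fronds (63.0, others 10.7 to 16.6) and for Sp10g01041 in roots (4.43, others 0.363 to 1.00). No-phosphate frond library 8 was high for Sp01g01360 (102.1 FPKM), Sp03g00871 (0.562) and Sp09g00776 (55.8), and library 5 for Sp10g00286 (25.2). No-phosphate root library 5 was high for Sp02g01212 (2.46 FPKM, others 0) and Sp08g00804 (9.53, others 1.51 to 2.52). Control root library 1 was high for Sp01g01589 (939.8 FPKM) and Sp02g00888 (122.0) and low for Sp11g00243 (110.7). Control root library 3 was high for Sp02g00736 (1.30 FPKM), Sp04g00300 (30.7), Sp08g00770 (0.140), Sp10g00918 (2.67), Sp12g00463 (2.80) and Sp13g00367 (2.52), and control root library 4 for Sp03g00871 (38.0). In control fronds, library 1 was high for Sp01g01671 (27.6 FPKM) and library 3 for Sp05g00658 (32.9), and library 2 was low for Sp13g00300 (2.52).

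On their first component, root libraries 1 and 5 lay out of place. The 70 genes of the root response were matched or exceeded in 5 of 35 splits of the 8 root libraries, the real one included, so chance is not excluded. The highest other split, libraries 1, 6, 7 and 8 against 2, 3, 4 and 5, called 1113 and exchanges libraries 1 and 5. Libraries 1, 5, 7 and 8 against the rest called 706, and libraries 1, 3, 7 and 8 against the rest 286. On the first component library 6 (14.4) lay nearer to library 1 (9.77) than to libraries 7 and 8 (34.9 and 41.3). These counts point to a structure of the samples, but not to 1 particular to an exchange of libraries 1 and 5. A swap of the 2 cannot be told apart from other causes: the first component of all genes in roots (34.5% of the variance) places library 1 at 9.77, nearer the mean of libraries 6 to 8 (30.2) than of 2 to 4 (-28.2), and library 5 at -15.6, nearer the latter, but on the 732 genes called in fronds library 1 scores -0.0709, below the lowest of libraries 6 to 8 (0.161, SD 0.0990). Frond-rich genes were visible in library 5 at a median of 0.967% of the frond level, and some were also raised in control root library 3. Whether frond tissue was their source was not tested. Taking that share of frond signal out of library 5 left the score of library 5 on the genes called in fronds at -0.0610 (before, -0.0504). The first component was not recomputed, so frond tissue was not tested as a cause of its place there. Its 9000741 reads lay inside the range of the others, so size did not set it apart. A swap, a wrong label of library 5 alone, frond signal in it from tissue or another source, and a difference between flasks stay open. Without libraries 1 and 5, 1604 root genes were called, a count that picking libraries because they stand apart raises by itself.

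Of 19 clock genes listed after the data were seen, 6 fell, 2 rose and the other 11 did not pass in fronds (camera downwards at adjusted p = 0.0279, and adjusted p = 0.244 with an estimated correlation), and in roots 1 fell (adjusted p = 0.0571, and 0.388), and without the 2 members already seen the list was not called in fronds or roots (adjusted p = 0.0561 and 0.373). The called ones include both GIGANTEA homologs (Sp05g00030, 76.6 ± 14.8 to 38.3 ± 3.46 FPKM, adjusted p = 0.0411; Sp05g00031, 26.4 ± 5.67 to 11.2 ± 0.847 FPKM, adjusted p = 0.0119) and REVEILLE 1, which rose (Sp09g00236, 44.5 ± 5.98 to 105 ± 40.9 FPKM, adjusted p = 0.0282). A scaling factor shifts all genes of a library the same way, whereas the called clock genes went both ways, which argues against scaling as the whole cause. Rescaled FPKM, with which 6 still fell and 2 rose, decides little. It moved the median frond change of all genes only from 0.00851 to -0.0287. Harvest of the treatments at another time of day could give such a pattern, and within groups the clock score followed the other 724 genes called in fronds over 16 libraries (Pearson r = 0.892, permutation p = 1e-05, adjusted p = 2e-05; Spearman rho = 0.924, permutation p = 4e-05, 2 relations; r = 0.903 without the 2 libraries farthest out), the first p being the smallest the permutations can give. Random sets of 8 called genes followed the rest as closely, with a median r of 0.849 and the clock set at percentile 71.3, so the relation is not shown to be special to clock genes, and time of day and phosphate cannot be told apart here.

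Between tissues, 3 lists differed by camera on the interaction: ribosomal proteins (adjusted p = 3.83e-11), DNA replication and cell cycle (adjusted p = 1.41e-05) and flavonoid synthesis (adjusted p = 0.0402), all lower in the root response, and none was called with an estimated correlation (adjusted p = 0.827, 0.597 and 0.827). Rescaled FPKM left the medians of the first 2 at -0.36 and -0.25 but hardly moved the interaction of all genes (median 0.00284), so that scaling stays untested here. Spread between libraries that the genes of a list share could account for the ribosomal list. Of 100 permutations of the treatment within tissues, the real labels included, 14 gave a list mean as far from that of all genes (real -0.327, highest other 0.588). For the cell cycle list 2 of 100 did, the real labels included (real -0.294, highest other 0.329). With both tissues permuted together by column number 3 of 35 did, the real labels again included (highest other 0.336). Shared spread and a response that differs between tissues therefore cannot be told apart.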

How the results depend on the processing

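The alternatives were fixed before the data were examined unless said otherwise. Named tissue genes kept their direction and call in each alternative run for named genes. The block by column number, the fit of only the compared libraries and the change of at least 1 were not run for named genes. The root libraries alone called 0 genes, so each named root gene would lose its call there. No called list reversed, nor any named gene called in the main fit or the alternative. For other named genes, among them those of the interaction, a changed sign was not recorded. Named frond genes lost their call in 9 of 259 planned checks, 121 of 704 with a library left out and 12 of 132 added after the data were seen, named root genes in 27 of 131, 138 of 352 and 2 of 66. With a library left out, frond calls ranged from 153 (without no-phosphate frond library 5) to 971 (without no-phosphate root library 6), root calls from 0 (without no-phosphate root library 7 or 8) to 791 (without no-phosphate root library 5), interaction calls from 0 to 116 (without no-phosphate root library 6) and tissue calls from 9269 to 10130. Root calls were 36, 40, 42 and 45 without control frond libraries 1 to 4 and 36, 29 and 46 without no-phosphate frond libraries 6 to 8, and interaction calls 2, 1 and 3 without control frond library 1 or 3 or no-phosphate frond library 7. The correlation ranged from 0.173 (without no-phosphate root library 6) to 0.405, called lists from 2 (without no-phosphate frond library 5) to 4 in fronds, 1 (without control root library 4) to 9 (without control root library 1) in roots and 2 to 4 for the interaction, and stayed at 5 for tissues. Requiring a change of at least 1 left 167 frond, 21 root and 4604 tissue genes, by construction. Fitting only the compared libraries gave 1772 frond and 0 root genes, and the median SD of a gene was 0.189 in both frond groups and 0.237 and 0.262 in control and no-phosphate roots, which share 1 estimate in the fit over all libraries. Root calls were 40 without trend and robust prior, 25 with FPKM rescaled to the same sum in each library, 20 with quantile normalization and 127 with a mean of at least 5 FPKM, and the cause was not tested. Interaction calls were 2 with rescaled FPKM. With the estimated correlation 0 lists were called in each of the 4 contrasts, photosynthesis between tissues included, so a call lost there decides little. With a pseudocount of 0.1 the frond lists were 2. At the preset correlation the frond calls of DNA replication and SPX signalling were lost in 5 and 4 of 21 alternatives, the root calls of phosphorus scavenging, root cell markers, DNA replication, glycolytic bypass and starch in 13, 7, 3, 2 and 1, the interaction call of flavonoid synthesis in 10 and the tissue call of lignin and suberin in 1, and the other list calls in none. Of the alternatives added after the data were seen, voom on the recovered reads called 139 root genes and 2 interaction genes with the library sizes implied by the FPKM, and 2 interaction genes with summed reads. Leaving out root libraries 1 and 5 gave 1604 root genes, 6 interaction genes and 5 interaction lists. No paired analysis was possible for the frond and root responses because control and no-phosphate columns share no number, and the planned blocks by labelled replicate were not run. Frond and root columns do share numbers, but these do not show a pairing: deviations from the group means correlated at -0.116 to 0.147 over the 8 numbers, and 3 of 8 frond and 2 of 8 root libraries correlated best with their own number. Numbers 6 and 7 matched best both ways, so a pairing is not excluded. With the column number as a replicate block, chosen after the data were seen, 2 interaction genes and 9700 tissue genes were called, with 3 and 5 lists. Permuting both tissues together by number, 1 of 35 splits gave as high a covariance of the responses (0.0410, highest other 0.0309) and 4 as high an r, the real split included in both. In each split 0 interaction genes were called. The frond count (732, highest other of 35 splits 2) and the tissue count (9929, highest other 1) were each reached in 1 of 35 splits, the real one. That is the smallest share the splits can give, so chance is argued against but not excluded. For the interaction 0 genes were called by limma, so that 100 of 100 permutations are as large by construction (highest other 39) and decide nothing, and its 1843 genes at an unadjusted p under 0.05 were reached in 8 of 100 (highest other 2792), so chance is not excluded. Depth limits low genes: 3 reads over 1 kb were worth 0.213 to 0.507 FPKM.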

Other observations

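The tests of this part were chosen after the data were seen. Among 293 Pfam families with at least 10 tested genes, 7 were shifted in fronds and 17 in roots by camera, and none held with an estimated correlation (adjusted p = 0.995 and 0.851 for the families named here). HSP70 proteins were up in fronds (13 members, median log2 change 0.55, 4 risen, adjusted p = 1.47e-05) and in roots (median 0.43, none called singly, adjusted p = 2.09e-05). Actins were up in fronds (14 members, median 0.31, 3 risen, adjusted p = 0.0182). The GTPase domain of tubulins had a median of 0.37 over 19 genes in fronds (adjusted p = 0.0248) and -0.38 in roots (adjusted p = 0.000449), and kinesins had -0.21 over 44 genes in roots (adjusted p = 0.0168). Pentatricopeptide repeat proteins, which process organelle RNA, had -0.15 over 354 genes in roots (adjusted p = 2.09e-05).

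Sulfate assimilation was a hypothesis from the rises of the adenylylsulfate reductases. Of 28 genes on a keyword list, 5 rose and 1 fell in fronds, with serine acetyltransferase 5 (Sp08g00934) going from 7.64 ± 1.23 to 17.8 ± 5.55 FPKM and a sulfite reductase (Sp01g00257) from 45.0 ± 13.4 to 18.0 ± 3.07 FPKM. Camera over 3 added lists gave adjusted p = 0.0503 upwards, which misses the threshold, and adjusted p = 0.244 with an estimated correlation. In roots 1 rose and none fell, with adjusted p = 0.0465, and adjusted p = 0.271 with an estimated correlation. Without the 3 members already seen to rise in fronds, both reductases and sulfate transporter 1.3, the list was not called in fronds or roots (adjusted p = 0.625 and 0.268).

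Copper supply was a further hypothesis from the fall of the copper transporters in fronds. Camera gave no call for the list of 19 genes (adjusted p = 0.918), with 2 fallen and 1 risen, the copper carrier CCH (Sp04g00048, 94.6 ± 14.3 to 138 ± 13.4 FPKM). In roots the transporter Sp06g01301 went from 1351 ± 909.8 to 765 ± 753 FPKM (adjusted p = 0.411), a spread between libraries too wide to tell a change.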
